A study of Mus musculus with 15 samples.

How the data were processed

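Midbrain total RNA of 15 samples was profiled, 8 WT and 7 A30P. Per the labels' protocols, tissue was dissected on ice and frozen, RNA was extracted with Trizol, and libraries were made from 1 µg of total RNA with a TruSeq small RNA kit, while per the file headers the library columns begin with NEB, so which kit was used is uncertain. Per the submitters' processing notes, the genome build was mm9 and DESeq was used, without a version. The aligner, the counter and the miRNA annotation are not given in the sources used here.

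The authors deposited a single table for the whole series. Per the file headers it held, for each of 396 miRNAs (4 of them under a combined name), a value per library, the authors' log2 fold change with its standard error, a p-value, an adjusted p-value and a mean for each group. The columns taken as WT are named CT there, read as the control, and were matched to the WT samples by number. The per-library signal values are read counts that the authors had divided by a size factor per library. In each library every value was a whole multiple of a single step, and 100% of values came out whole (within 1e-05), so whole reads were recovered for all 15 libraries. Scaling the values again by the median ratio, which rests on the 92 miRNAs with reads in every library, moved the median log2 fold change by 0.01. The deposited group means have the unit score here, because their scale is not stated, and were used only for the implied share of listed miRNAs. Read as means of RPM values, they were fitted as weighted sums of the recovered reads (largest deviation 14.2 in WT and 12.9 in A30P), which gives that share per library. The adjusted p-value deposited by the authors equals a Benjamini-Hochberg adjustment over all listed miRNAs. Their log2 fold changes are printed only where the authors' deposited table is named. No file gave the total reads of a library directly, so depth here means the reads of listed miRNAs.

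Since the values were normalized, the main test was limma (version 3.58.1, trend and robust) on log2(value + 1) for miRNAs with a mean of at least 1 in either group, which all 396 passed. Fold changes are on that scale, which understates changes of low miRNAs and, for miRNAs without reads in shallow libraries, reflects the pseudocount of 1. P-values were adjusted by Benjamini-Hochberg. Values per group are the mean ± SD of normalized counts. No covariate was used, since the design text names none. The count tests edgeR (4.0.16), DESeq2 (1.42.0) and limma-voom were run on the recovered reads as alternatives. edgeR with TMM scaling tested 313 miRNAs and called 173. R was version 4.3.3. Single values were compared by exact permutation over the 6435 splits of 7 against 8 (scipy 1.17.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3), and plots were drawn with matplotlib 3.10.9.

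The 17 miRNA lists and the rule for named miRNAs were fixed before the data were examined, from general knowledge of the tissue. The 16 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The text names every arm of the miR-101 family, the members of the alpha-synuclein and dopamine lists with a mean of at least 10, the 10 miRNAs ranked first by p in each direction with a mean of at least 10, and up to 3 members of each other list by smallest p among those with a mean of at least 10. This gave 64 miRNAs. Others were named after their values were seen: the opposite arms of hairpins, members behind small list counts, let-7f-5p, and the miRNAs that open the other observations.

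The fits were tested on simulated counts with the real WT means, a dispersion of 0.15 and 200 of 396 miRNAs changed by 2 on the log2 scale. With equal depth limma recovered 100% of the changed miRNAs in both directions and called 0.510% of the unchanged ones lower. With the real depths of the A30P against WT comparison it recovered 58% of the higher and 100% of the lower miRNAs, called 16.8% of the unchanged ones lower and gave those a median log2 fold change of -0.60. edgeR with TMM scaling at the real depths recovered 97% and 89%, and called 10.7% of the unchanged ones lower. The simulated A30P counts were built from WT means, so the larger shifts in read shares of the real A30P libraries were not simulated. edgeR fitted 362 simulated miRNAs at the real depths, against 313 in the data. The rates therefore hold for the simulated counts only, and may be too favourable for the real comparison.

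Alternatives set before the data were examined were another rescaling, no filter or a mean of at least 10, pseudocounts of 0.1 and 10, the replicate number as a block, each library left out, other thresholds and the authors' adjusted p. Alternatives chosen after seeing the data were the count tests, scaling to the total of listed reads, TMM scaling, and fits without the 4 A30P libraries under 100000 reads or without WT libraries 1 and 8. To compare at equal depth, every library was thinned to 21731 reads in 20 draws and tested with edgeR. Hairpin positions and sequences came from GENCODE vM21 (GRCm38), matched by miRNA name, and 385 of the 396 miRNAs matched. The mm9 build was not used here.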

Results

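Small RNA sequencing was used to profile the midbrain miRNAome of C57BL/6 mice at 6 months of age. The series held 7 midbrain samples from mice with the A30P form of alpha-synuclein, labelled +/+ (replicates 1, 2, 3, 4, 6, 7 and 8), and 8 from wild-type mice (WT, replicates 1 to 8). Alpha-synuclein is a presynaptic protein, and A30P is a form of it linked to familial Parkinson's disease. The deposited table listed 396 mature miRNAs with a normalized count in each of the 15 libraries. The library columns taken as WT are named CT in that table, which was read as the control of the comparison, and were matched to the WT samples by number. The labels did not state that each sample came from its own animal, so p-values measure the spread between these samples, which may in part be technical.

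The A30P libraries were shallower than the WT libraries. The reads assigned to listed miRNAs ranged from 724813 to 9762286 in WT (median 5081436.5) and from 21731 to 3500431 in A30P (median 92827), a difference of -1.41 on the log10 scale (exact permutation test, two-sided, p = 0.00155). A30P replicates 4, 7, 1 and 2 held 21731, 27348, 65053 and 92827 reads, replicates 3 and 8 held 355333 and 441177, and replicate 6 held 3500431. Between 122 and 395 of the miRNAs were detected per A30P library and between 375 and 396 per WT library (exact permutation test, p = 0.000932). In A30P replicate 4 a single read was worth 56.4 normalized counts, and a listing at 0 there allows a level of up to 169 normalized counts (3 reads). If the deposited group means are means of RPM values, scaled to a library total, a fit of them placed the listed miRNAs at 55.0% to 71.1% of that total in WT libraries and at 19.7% to 52.4% in A30P libraries, without overlap. In WT libraries a single read was worth 0.0848 to 0.806 normalized counts. The column names carried one letter tag in all WT libraries and another in all A30P libraries. They also all began with NEB, whereas the labels name a TruSeq kit, so the library kit is uncertain. What the tag stands for is not given in the sources used here, and if it marks a run or batch, that batch and the genotype cannot be told apart.

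The first comparison addressed which miRNAs differed in midbrain between A30P and WT mice. miR-148a-3p, a regulator of lipid metabolism genes in liver, and miR-151-3p, a miRNA encoded within the focal adhesion kinase gene, were the most strongly up-expressed miRNAs in A30P midbrain. miR-148a-3p rose from 4961 ± 2445 normalized counts (SD, n = 8) in WT to 461355 ± 259505 (SD, n = 7) in A30P, a 93.0-fold ratio of means, and miR-151-3p rose from 3134 ± 2346 to 323037 ± 215802, a 103-fold ratio. The ratio for miR-151-3p rests mainly on the shallower A30P libraries, since the deepest, replicate 6, held 13577 normalized counts. miR-708-3p, miR-381-3p, miR-30a-3p, miR-1981-5p, miR-10b-5p, miR-30e-3p, miR-184-3p and miR-379-5p were the other up-expressed miRNAs among the first 10 by p. By p, the first falls were those of miR-125a-5p and miR-125b-5p, mammalian homologs of the lin-4 miRNA, of miR-328-3p and of the neuronal miR-128-3p. miR-125a-5p fell from 28456 ± 11593 normalized counts in WT to 1230 ± 638 in A30P, and miR-125b-5p from 34595 ± 8019 to 1086 ± 1201.

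In all, 314 of the 396 miRNAs passed adjusted p 0.05 by limma on log2(value + 1), 33 higher and 281 lower in A30P, with a median log2 fold change over all miRNAs of -2.57. When edgeR's quasi-likelihood test was run on the recovered whole reads with TMM scaling, 173 of 313 tested miRNAs passed, 62 higher and 111 lower. Higher calls were 10.5% of calls in the first fit, 35.8% in edgeR with TMM scaling and 47.0% in limma-voom with TMM scaling (77 higher, 87 lower). All 33 higher calls and 111 of the 281 lower calls were also called in that direction by edgeR with TMM scaling. Of the 33 higher calls, 22 remained with scaling to the total of listed reads, 23 without the 4 A30P libraries under 100000 reads and 19 by the authors' deposited adjusted p. Only 96 of the 281 lower calls had a WT mean at or above the 169 normalized counts that a listing at 0 allows in the shallowest A30P library. For the other 185 a fall of the whole A30P group was not detectable library by library at this depth. Relative to the deposited scaling, TMM scaling moved the median log2 fold change of all miRNAs by 0.74 and scaling to the total of listed reads by -0.35. The limma median also depended on the pseudocount, at -4.34 with 0.1 and -1.07 with 10. It was -0.74 in edgeR and -0.13 in limma-voom, each with TMM scaling over 313 tested miRNAs.

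Among the 10 miRNAs ranked first by p in the higher direction, the log2 fold change of miR-148a-3p was 6.44 (SE 0.47, adjusted p = 4.1e-09), that of miR-708-3p was 4.43 (SE 0.34, adjusted p = 4.1e-09) and that of miR-151-3p was 6.31 (SE 0.63, adjusted p = 2.2e-07). miR-708-3p rose from 641 ± 158 to 14754 ± 5607 normalized counts, and every A30P library lay above every WT library for these 3 miRNAs. miR-184-3p, a miRNA abundant in eye epithelia, was listed at 7.63 ± 1.80 normalized counts in WT and rose to 364 ± 264 in A30P (log2 fold change 4.91, SE 0.70, adjusted p = 7.0e-06). miR-381-3p rose 5.48-fold by the ratio of means, miR-379-5p 4.55-fold, miR-30a-3p 11.6-fold, miR-30e-3p 6.35-fold and miR-1981-5p 15.1-fold, and miR-10b-5p had a log2 fold change of 3.20. Among all 33 higher calls, 32 had reads in all 7 A30P libraries.

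The 10 miRNAs ranked first in the lower direction were miR-125a-5p (log2 fold change -4.63, SE 0.34, adjusted p = 4.1e-09), miR-328-3p (-4.52, SE 0.35, adjusted p = 4.2e-09), miR-125b-5p (-5.52, SE 0.44, adjusted p = 7.2e-09), miR-128-3p, let-7d-5p, miR-433-3p, miR-30d-5p, miR-26a-5p, miR-191-5p and let-7e-3p. miR-128-3p fell from 45404 ± 11625 to 5405 ± 2575 normalized counts, let-7d-5p from 13052 ± 4835 to 998 ± 341, miR-26a-5p from 39027 ± 16193 to 2207 ± 2481 and miR-433-3p from 6742 ± 1267 to 299 ± 261. All of these except let-7e-3p had reads in all 7 A30P libraries. let-7e-3p had reads in 1 of them, so its log2 fold change of -5.32 depends on the pseudocount. miR-125b-5p, miR-128-3p and miR-26a-5p each derive from 2 hairpins with the same mature sequence, so reads cannot be assigned to either hairpin. The let-7 members differ by few bases, and how the authors split reads between them is not given in the sources used here.

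**Figure D1:**
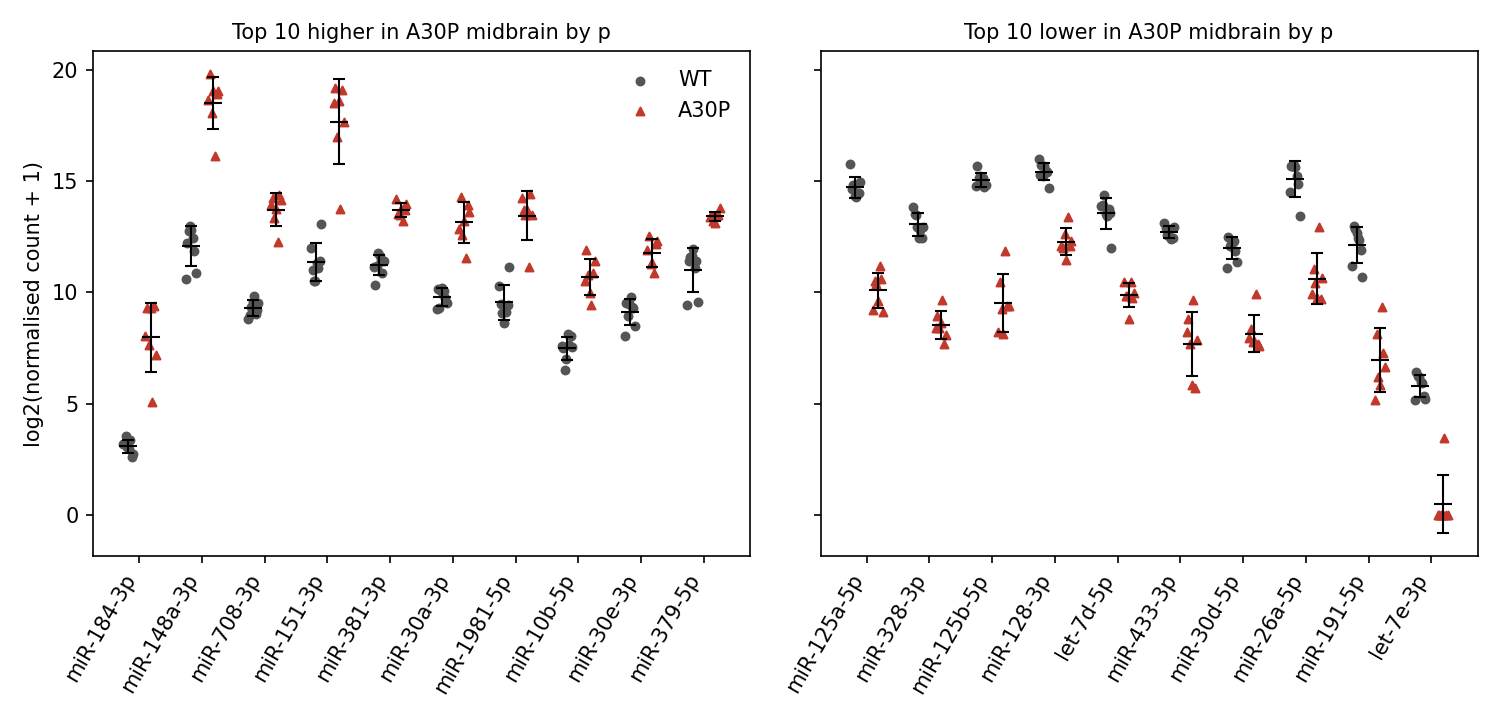
Values of log2(normalised count + 1) for the 10 miRNAs ranked first by p in each direction, with each library as a point (WT grey circles, n = 8; A30P red triangles, n = 7) and the mean and SD in black. miR-148a-3p and miR-151-3p reach the highest A30P levels, and let-7e-3p has reads in 1 A30P library.

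The share of listed reads taken by miR-148a-3p and miR-151-3p does not depend on the scaling. miR-148a-3p took 0.676% ± 0.242 (SD, n = 8) of reads in WT and 37.0% ± 12.7 (SD, n = 7) in A30P, and miR-151-3p 0.554% ± 0.631 and 24.8% ± 12.9 (exact permutation tests, p = 0.000311 for each, the smallest that the permutations can give). The lowest A30P share of miR-148a-3p was 11.6% in replicate 6 (Wilson 95% interval 11.6% to 11.7%), and the highest WT share was 0.978% in replicate 4 (0.970% to 0.985%). For miR-151-3p the groups almost touched, with a lowest A30P share of 2.23% in replicate 6 and a highest WT share of 2.06% in replicate 8. Together both miRNAs took 13.9% to 80.1% of the reads of an A30P library and 0.842% to 2.51% of a WT library. The intervals cover counting error only, since reads were not counted by molecular identifiers.

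**Figure D2:**
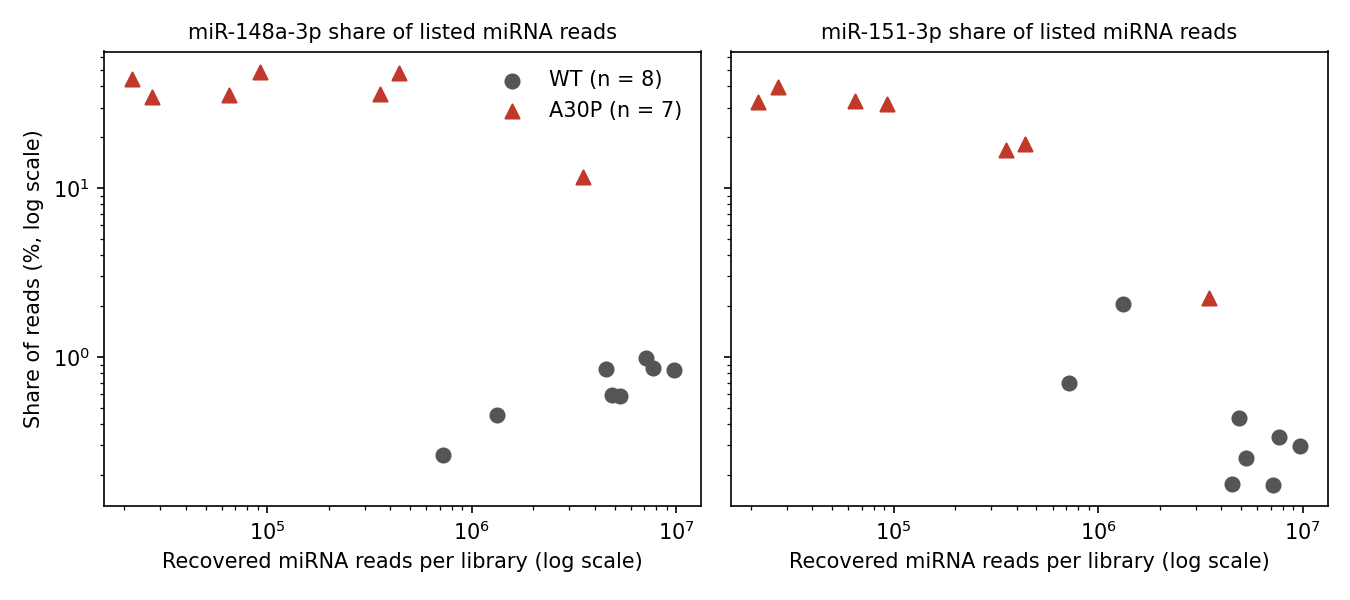
Share of listed miRNA reads (percent, log scale) taken by miR-148a-3p (left) and miR-151-3p (right) against the recovered reads per library (log scale), with WT as grey circles (n = 8) and A30P as red triangles (n = 7). The A30P libraries lie at 11.6% to 48.6% for miR-148a-3p, and the WT libraries at 0.263% to 0.978%.

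The hairpins were placed by name in the GENCODE vM21 annotation of GRCm38, which is not the mm9 build named in the submitters' processing notes. Mir148a lies on chromosome 6 from 51269812 to 51269910 on the minus strand, with no annotated host gene on that strand. Mir151 lies on chromosome 15 from 73254815 to 73254882 (minus strand) in an intron of Ptk2, and Mir708 on chromosome 7 from 96249424 to 96249532 (plus strand) in an intron of Tenm4. Mir10b lies on chromosome 2 from 74726070 to 74726137 (plus strand) in introns of Hoxd3 and Hoxd4. Mir125a lies on chromosome 17 from 17830812 to 17830879 (plus strand), overlapping an exon of Spaca6, and Mir101a on chromosome 4 from 101346945 to 101347027 (minus strand), overlapping an exon of the long noncoding RNA E130102H24Rik.

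Both arms were listed for 93 hairpins. In 13 of them the arms passed the test in opposite directions, with the 3p arm higher in 9 and the 5p arm higher in 4. For miR-30a the 3p arm rose from 912 ± 232 to 10596 ± 5910 normalized counts while the 5p arm fell from 1483 ± 903 to 286 ± 341 (log2 fold change -3.31, adjusted p = 0.0082). For miR-379 the 5p arm rose from 2411 ± 1162 to 10979 ± 1664 and the 3p arm fell from 289 ± 132 to 18.8 ± 22.8 (log2 fold change -5.20, adjusted p = 0.00012). In 4 of the 13 hairpins, miR-30a, miR-30e, miR-379 and miR-409, the WT mean of the lower arm was at or above 169 normalized counts. In the other 9, which include miR-148a, miR-151 and miR-708, the lower arm was below that level in WT. The falls of miR-30a-5p and miR-30e-5p did not pass in edgeR with TMM scaling (log2 fold change -0.92 and -0.65, adjusted p = 0.143 and 0.345).

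**Figure D3:**
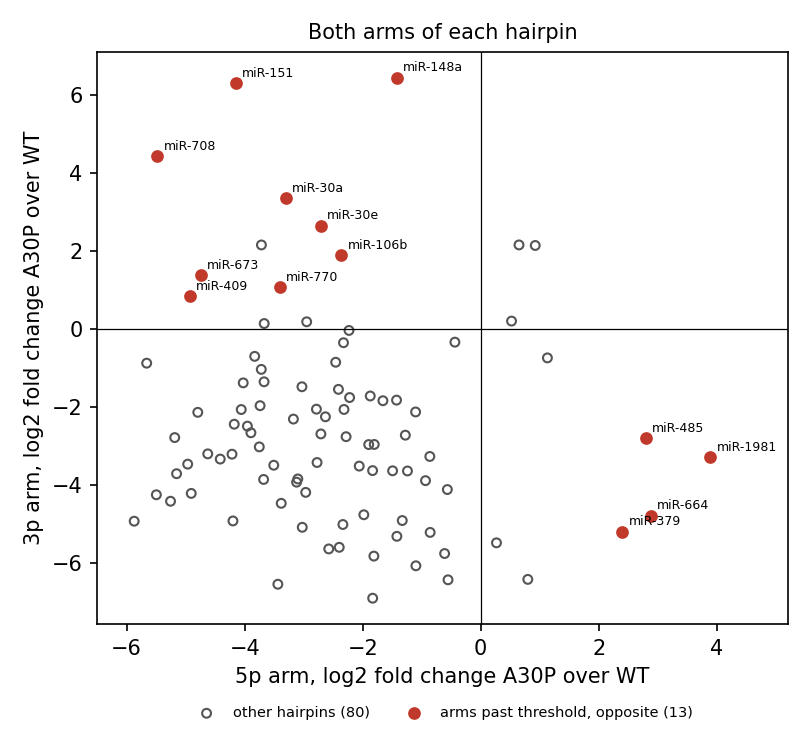
Log2 fold change (A30P over WT, log2(value + 1) scale) of the 3p arm against the 5p arm for 93 hairpins with both arms listed. Red points mark the 13 hairpins with both arms past adjusted p 0.05 in opposite directions, and open circles the other 80.

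The second comparison concerned miR-101a, the miRNA that the series title links to synaptic plasticity and synucleinopathy. miR-101a-3p had a mean of 1972 ± 955 normalized counts (SD, n = 7) in A30P and 945 ± 940 (SD, n = 8) in WT, a 2.09-fold ratio of means. The log2 fold change was 1.60 (SE 0.73), and the difference did not pass the threshold by limma (adjusted p = 0.0503) or by an exact permutation test of the log2 values (two-sided, p = 0.0709). Its share of reads was 0.196% in A30P and 0.119% in WT (exact permutation test, p = 0.1998). The difference passed in edgeR with TMM scaling (log2 fold change 2.58, adjusted p = 0.00042), and in the authors' deposited table, where the log2 fold change was 2.96 with an adjusted p of 0.00074. With the deposited size factors it did not pass in edgeR (log2 fold change 1.07, adjusted p = 0.120) or DESeq2 (1.07, 0.133). The lowest WT values were 82.3 in replicate 1 and 94.4 in replicate 8, against 470 to 2585 in the other WT libraries, and the log2 fold change was 0.73 (adjusted p = 0.245) without those 2 libraries. Among the A30P libraries, replicate 4 was lowest at 282 normalized counts from 5 reads, and without it the log2 fold change was 2.02 (adjusted p = 0.0138). The call was also made without WT replicate 3, 4 or 5 (adjusted p = 0.0468, 0.0238 and 0.0193). miR-101b-3p was at 22.2 ± 23.5 in A30P, with reads in 4 of 7 libraries, and at 34.2 ± 27.7 in WT (log2 fold change -1.63, adjusted p = 0.152, 0.69 in edgeR with TMM scaling, and -2.07 with scaling to the total of listed reads, where adjusted p was 0.0481). Of the 2 measured members of the miR-101 family, 0 passed by limma, also when adjusted over the list alone, and 1 passed in edgeR with TMM scaling.

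**Figure D4:**
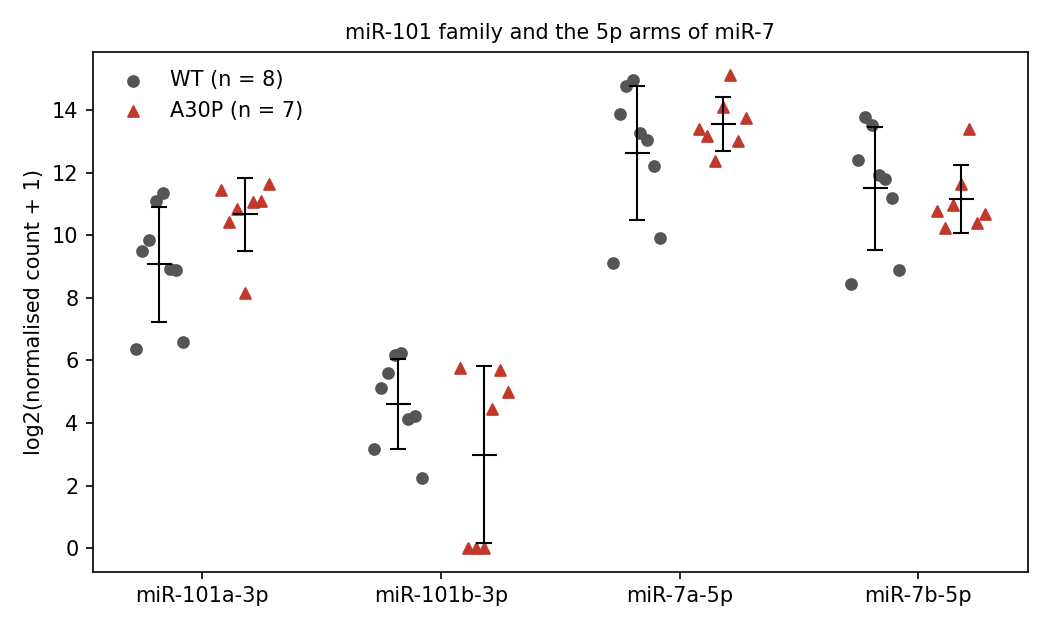
Values of log2(normalised count + 1) for miR-101a-3p, miR-101b-3p, miR-7a-5p and miR-7b-5p, with each library as a point (WT grey circles, n = 8; A30P red triangles, n = 7) and the mean and SD in black. For miR-101a-3p the WT libraries span 82.3 to 2585 normalized counts and the A30P libraries 282 to 3202.

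The third comparison set the fixed miRNA lists between the genotypes. By limma, over all 396 miRNAs 33 rose and 281 fell, so the counts per list are to be read against that. Those counts are also by limma unless another test is named. The list of miRNAs reported to bind the alpha-synuclein mRNA was matched by miRNA name and so holds both arms of a hairpin. Of its 8 measured arms 0 rose, 4 fell and 4 did not pass (4 when adjusted over the list alone), and all 4 falls were of 3p arms from the miR-7 and miR-34 families. The abundant members miR-7a-5p (14324 ± 10143 in A30P, 12372 ± 11738 in WT) and miR-7b-5p (3125 ± 3432 and 5242 ± 5082) did not pass by limma (adjusted p = 0.259 and 0.668), and miR-7b-5p passed downward only without WT libraries 1 and 8 (log2 fold change -1.29, adjusted p = 0.0324). For miR-7a-5p the difference passed with TMM scaling in edgeR (log2 fold change 1.74, adjusted p = 0.0066), and the log2 fold change was -0.13 without WT libraries 1 and 8. miR-153-3p (12.8 ± 13.4 in A30P, 64.1 ± 66.7 in WT) and miR-34c-5p (99.7 ± 109 and 385 ± 407) did not pass either (log2 fold change -2.32 and -2.71, adjusted p = 0.0593 and 0.0628), but passed downward with scaling to the total of listed reads (adjusted p = 0.0145 and 0.0197). The falls were in miR-7a-1-3p, miR-7a-2-3p, miR-34b-3p and miR-34c-3p, all with a WT mean below 169 normalized counts, and that of miR-7a-1-3p did not pass in edgeR with TMM scaling (adjusted p = 0.203).

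Of 8 miRNAs linked to dopamine neurons or Parkinson's disease, 1 rose, 5 fell and 2 did not pass, with 7 past when adjusted over the list alone. miR-184-3p rose. miR-124-3p, the most neuron-restricted of brain miRNAs, fell from 1405 ± 654 to 119 ± 111 normalized counts (log2 fold change -4.47, SE 0.92, adjusted p = 0.00028). miR-132-3p, which is induced by neuronal activity, fell from 683 ± 448 to 93.3 ± 110 (log2 fold change -3.89, adjusted p = 0.0018), with a log2 fold change of -1.38 in edgeR with TMM scaling (adjusted p = 0.0411) and of -0.49 in the authors' deposited table (adjusted p = 0.585). miR-132-5p did not pass, at 204 ± 59.4 in A30P and 459 ± 260 in WT (log2 fold change -0.94, adjusted p = 0.118, and 0.26 in edgeR with TMM scaling), but passed downward with the deposited size factors in edgeR and DESeq2 (adjusted p = 0.0327 and 0.0216), with scaling to the total of listed reads (0.0113), without WT replicate 8 (0.0358) and without WT libraries 1 and 8 (0.0095). miR-218-5p, a motor neuron miRNA, was at 510 ± 363 in A30P and 2133 ± 1765 in WT and did not pass (log2 fold change -2.59, adjusted p = 0.0529). Its difference passed downward with the deposited size factors in edgeR and DESeq2 (adjusted p = 0.0102 and 0.0045), with scaling to the total of listed reads (0.0128), with a pseudocount of 10 (0.0373), without WT libraries 1 and 8 (0.0183) and without WT replicate 1 or 8 or A30P replicate 1, 2 or 6 (0.0295 to 0.0488), while the authors' deposited table had a log2 fold change of 0.62 (adjusted p = 0.533). The falls of miR-212-5p, miR-124-5p and miR-212-3p did not pass in edgeR with TMM scaling (adjusted p = 0.0993, 0.592 and 0.998).

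Of 20 activity and synaptic plasticity miRNAs, 3 rose, 14 fell and 3 did not pass, and of 21 neuron miRNAs 1 rose, 16 fell and 4 did not pass (17 past in each list when adjusted over the list alone). Beside miR-128-3p and miR-125b-5p, miR-434-3p fell from 8174 ± 3553 to 366 ± 415 normalized counts (log2 fold change -5.76, SE 1.01, adjusted p = 6.4e-05) and miR-129-2-3p from 354 ± 219 to 36.3 ± 83.1 (adjusted p = 9.7e-05, and 0.0550 in edgeR with TMM scaling). miR-485-5p, miR-129-5p and miR-125b-1-3p rose, against most members of these lists, and the rises of miR-129-5p and miR-125b-1-3p did not pass with scaling to the total of listed reads (adjusted p = 0.476 and 0.452). In the authors' deposited table none of the 3 passed, with log2 fold changes of -0.49, 0.48 and -0.18 (adjusted p = 0.329, 0.506 and 0.648). The WT mean was at or above 169 normalized counts for 5 of the 14 falls and for 7 of the 16. In edgeR with TMM scaling, 3 of 16 tested activity and plasticity miRNAs rose and 4 fell. Of 17 tested neuron miRNAs, 2 rose and 6 fell there.

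By limma 281 of all 396 miRNAs were called lower, with a median log2 fold change over all miRNAs of -2.57. The size of that median depended on the pseudocount and the scaling, as given above. Markers of other cell types moved with these miRNAs. Against the remaining miRNAs neither the microglia and immune list nor the astrocyte list passed by camera (adjusted p = 0.996 and 0.542). All 4 microglia and immune miRNAs and all 8 astrocyte miRNAs fell, with median log2 fold changes of -4.37 and -3.57, and as many passed when adjusted over the list alone. Examples were miR-150-5p of lymphocytes (496 ± 130 to 38.7 ± 70.6 normalized counts), miR-21a-5p (2108 ± 1632 to 120 ± 119), miR-146a-5p (444 ± 222 to 54.4 ± 60.1), miR-29a-3p (3249 ± 2212 to 181 ± 156) and miR-23a-3p (201 ± 129 to 25.3 ± 41.4). In the authors' deposited table miR-21a-5p, miR-146a-5p and miR-23a-3p did not pass (log2 fold change -0.68, -0.76 and 0.0566, adjusted p = 0.476, 0.211 and 0.951). In edgeR with TMM scaling 3 of 4 and 4 of 7 tested members fell. Among 4 oligodendrocyte miRNAs 2 fell, both also when adjusted over the list alone. miR-338-5p went from 2289 ± 702 to 79.0 ± 89.2 (log2 fold change -5.87, SE 0.84, adjusted p = 7.9e-06), whereas miR-219a-2-3p, a miRNA of myelinating cells, was at 3177 ± 1573 in A30P and 4932 ± 1530 in WT (log2 fold change -0.73, adjusted p = 0.0593, and 0.46 in edgeR with TMM scaling). Its difference passed downward with scaling to the total of listed reads (-1.42, adjusted p = 0.0046), without WT libraries 1 and 8 (0.0351) and without WT replicate 1 or 3 or A30P replicate 2 or 6 (0.0195 to 0.0453). miR-338-3p fell from 189 ± 135 to 15.1 ± 22.4 (log2 fold change -4.93, adjusted p = 0.00038), with -0.00900 in the authors' deposited table (adjusted p = 0.992).

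Of 4 blood miRNAs, 1 rose, 2 fell and 1 did not pass (3 past when adjusted over the list alone). miR-451a, the erythrocyte miRNA, rose from 78.5 ± 32.8 to 602 ± 636 normalized counts (log2 fold change 2.03, adjusted p = 0.0327), a call that was lost without any of A30P replicates 1, 2, 4 and 7 or WT replicate 8 (adjusted p from 0.0596 to 0.0733) and with scaling to the total of listed reads (adjusted p = 0.0923). Without the 4 A30P libraries under 100000 reads its log2 fold change was -0.07. miR-486a-3p fell from 21.7 ± 15.9 to 4.61 ± 7.16 (adjusted p = 0.0020, and 0.545 in edgeR with TMM scaling), and miR-486b-5p, listed together with miR-486a-5p, was at 432 ± 209 in A30P and 634 ± 480 in WT (log2 fold change -0.40, adjusted p = 0.471), but passed downward in the authors' deposited table (-2.07, adjusted p = 0.00058). The median log2 fold change of this list by limma was -1.19 with the deposited scaling and -0.37 with TMM scaling. Of 5 vessel miRNAs, 1 rose and 4 fell, all also when adjusted over the list alone. Smooth muscle miR-143-3p rose from 3126 ± 1612 to 10046 ± 5859 (adjusted p = 0.0013, and 0.0595 with scaling to the total of listed reads), and endothelial miR-126a-3p fell from 6279 ± 3104 to 1201 ± 873 (adjusted p = 0.00044, and 0.0808 in edgeR with TMM scaling), as did miR-145a-5p (log2 fold change -3.51, adjusted p = 0.0018, and 0.201 in edgeR with TMM scaling). Neither fall passed in the authors' deposited table (log2 fold change 0.0625 and -0.41, adjusted p = 0.940 and 0.668). The same held without the 4 A30P libraries under 100000 reads (-1.37 and -1.84, adjusted p = 0.0710 and 0.0518). Of 5 choroid plexus and ependyma miRNAs 3 fell and 2 did not pass (3 past when adjusted over the list alone), with miR-204-5p going from 1545 ± 761 to 274 ± 247 (adjusted p = 0.00012, and 0.0562 in edgeR with TMM scaling).

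The epithelial and pituitary list and the Hox-linked caudal list had positive median log2 fold changes (2.03 and 2.31). miR-182-5p rose from 9.57 ± 5.42 normalized counts in WT to 329 ± 361 in A30P and miR-183-5p, of the same cluster, from 6.60 ± 3.05 to 232 ± 235, while miR-200b-3p was listed at 0 in all A30P libraries. miR-375-3p did not pass (122 ± 104 and 69.6 ± 53.6, adjusted p = 0.998), but passed upward with TMM scaling in edgeR (log2 fold change 2.36, adjusted p = 0.0015) and limma-voom (2.22, 0.0030), in the authors' deposited table (1.76, 0.0483) and without the 4 A30P libraries under 100000 reads (1.76, 0.0450). miR-10a-5p rose from 176 ± 43.2 to 915 ± 412 (log2 fold change 2.31, SE 0.43, adjusted p = 0.00011) and miR-10b-5p from 189 ± 61.5 to 1895 ± 1054, both encoded within Hox clusters, and miR-615-3p fell (adjusted p = 0.0015, and 0.838 in edgeR with TMM scaling). In the epithelial list 2 of 4 members rose and 1 fell, and in the Hox-linked list 2 of 3 rose and 1 fell (3 past in each when adjusted over the list alone). Of the 16 lists tested with camera these were the 2 past adjusted p 0.05, both upward (adjusted p = 0.0320 for each). Neither passed with an estimated correlation (adjusted p = 0.290 for each, unadjusted p = 0.0362 and 0.0281) or with TMM scaling (adjusted p = 0.131 and 0.117), and the epithelial list did not pass without WT libraries 1 and 8 (adjusted p = 0.149).

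Of 3 muscle miRNAs 1 rose, 1 fell and 1 did not pass (2 past when adjusted over the list alone). miR-206-3p rose 5.68-fold by the ratio of means, to 174 ± 116 (adjusted p = 0.0110, 0.0589 with scaling to the total of listed reads and 0.207 without the 4 A30P libraries under 100000 reads), and the list median of 0.08 turned to -0.60 with scaling to the total. In the authors' deposited table the log2 fold change of miR-206-3p was -0.0553 (adjusted p = 0.956). miR-1a-3p, at 1137 ± 913 in A30P and 992 ± 688 in WT, did not pass (log2 fold change 0.08, adjusted p = 0.921), but passed upward with TMM scaling in edgeR (1.59, 0.0140) and limma-voom (1.43, 0.0318) and in the authors' deposited table (3.06, 4.5e-07). Of 60 miRNAs of the imprinted Dlk1-Dio3 cluster 6 rose, 41 fell and 13 did not pass (47 past when adjusted over the list alone). The risers were miR-381-3p, miR-379-5p, miR-485-5p, miR-770-3p, miR-409-3p and miR-673-3p, of which the last 3 did not pass with scaling to the total of listed reads (adjusted p = 0.413, 0.785 and 0.325). miR-433-3p, miR-434-3p and miR-410-3p were among those that fell. The WT mean was at or above 169 normalized counts for only 16 of the 41 falls. In edgeR with TMM scaling 10 of 50 tested members of this cluster rose and 20 fell. Of 7 miRNAs of the miR-17-92 cluster and its paralogs 1 rose, miR-106b-3p, and 6 fell, among them miR-93-5p (98.0 ± 63.3 to 5.64 ± 7.50, log2 fold change -4.41), miR-20a-5p (46.7 ± 33.8 to 3.97 ± 7.66, -3.79) and miR-17-5p (21.5 ± 14.1 to 0.603 ± 1.03, -3.55), with 7 past when adjusted over the list alone. The falls of miR-20a-5p and miR-17-5p did not pass in limma-voom with TMM scaling (log2 fold change -0.74 and -0.24, adjusted p = 0.410 and 0.789), nor that of miR-20a-5p in the authors' deposited table (-1.05, adjusted p = 0.293). Only 1 of the 6 falls of this list had a WT mean at or above 169 normalized counts. In edgeR with TMM scaling 1 of 6 tested members rose and 3 fell. Of 15 let-7 family arms 0 rose, 11 fell and 4 did not pass (11 past when adjusted over the list alone). The WT mean was at or above 169 normalized counts for 6 of the 11 falls. In edgeR with TMM scaling 2 of 14 tested arms rose and 6 fell. let-7c-1-3p fell from 24.0 ± 6.82 to 0.672 ± 1.78 (adjusted p = 6.4e-07), with reads in 1 A30P library. let-7f-5p, the most abundant of them in A30P, was at 70585 ± 14746 in A30P and 51980 ± 25295 in WT (adjusted p = 0.102 by limma, and 0.00025 upward in edgeR with TMM scaling).

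**Figure D5:**
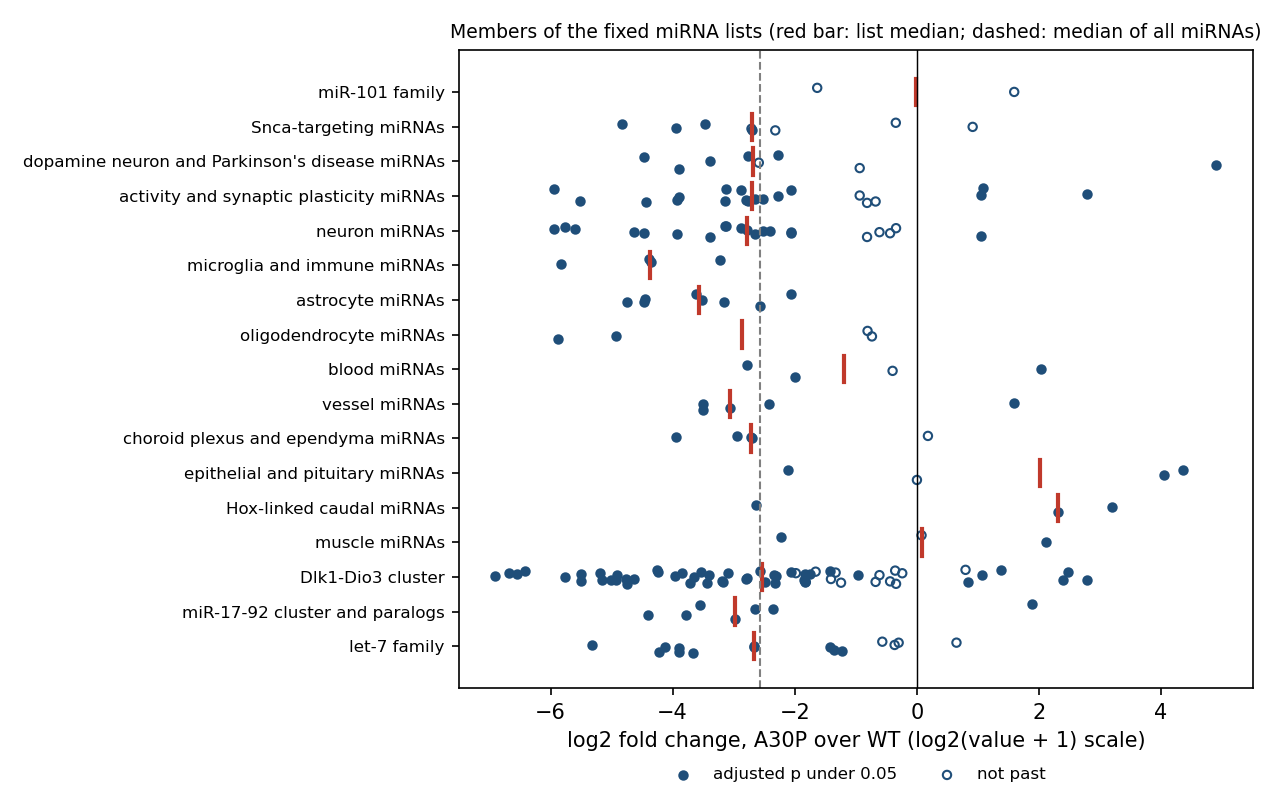
Log2 fold change (A30P over WT, log2(value + 1) scale) of each measured member of the 17 fixed lists, filled where adjusted p was under 0.05 by limma. Red bars mark list medians, the dashed line the median of all 396 miRNAs at -2.57, and the medians of the miR-101 family and muscle lists change sign with scaling.

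The other 14 lists did not pass in camera, which compares a list with the remaining miRNAs (smallest adjusted p = 0.427). For the alpha-synuclein, dopamine neuron, blood, vessel and choroid plexus lists the median and mean log2 fold changes were negative while camera placed them above the remaining miRNAs, and for the muscle list the mean was -0.01 with a median of 0.08. By fry, which tests whether members move on balance in one direction, 13 of 16 lists moved downward (adjusted p of 0.0065 or less) and the epithelial and Hox-linked lists upward. Since fry does not compare a list with the remaining miRNAs, the downward results follow the lower calls over all miRNAs. They do not set these lists apart.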

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

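The tests of scaling, of RNA from liver, of depth within each group, of the miRNAs testable at equal depth and of miR-101a-3p at equal depth were chosen only after the result was seen. The tests of thinning over all lower calls, of GC content, of hairpin arms and of other splits were set before, but the arm test of library preparation was given a further condition after its result was seen, as was the test of scaling, which changed how each was read, and the test of the miRNAs testable at equal depth was given another, which did not.

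The first pattern was the excess of lower over higher calls (281 against 33). Splits of the libraries were compared by calls in either direction, so they did not test the excess itself. The real split of the 15 libraries gave 314 calls, and 1 of 100 splits, the real one, gave as many, out of 6435 possible splits. The highest of the others, with 270, kept all A30P libraries together in one group. Chance is thus an unlikely source of the number of calls. For the lists it cannot be excluded, since 12 of 100 splits gave 2 lists past the threshold (highest of the others 2). Scaling stays open as a source of the excess, since with TMM scaling lower calls outnumbered higher calls clearly in limma (218 against 45) but were 111 against 62 in edgeR and 87 against 77 in limma-voom, while against GC content the Spearman rho between the GC of the arm's side of the hairpin and the log2 fold change was 0.0781 across 385 miRNAs, which are not independent replicates. At equal depth 45 of the 281 lower calls were made in the median of 20 thinned draws, but only about 89 miRNAs could be tested, so for the low miRNAs depth and genotype cannot be told apart. Of the lower calls that could still be tested (median 48), at least 91.7% remained in every draw, and of the lower calls that edgeR made at full depth at least 97.8% remained with the deposited scaling and 93.1% with TMM scaling. This argues against the number of reads as the whole cause for these miRNAs only. They were abundant enough to keep reads after thinning, so few losses were to be seen among them. Thinning also leaves in place anything that went with depth. With depth and scaling both changed, as few as 68.1% of the limma calls remained (median 80%), and 199 of the 206 losses over the draws were of miRNAs that edgeR with TMM scaling did not call lower at full depth either, so there scaling stays open, while genotype or a run that followed it stays open, untested.

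The second pattern was the share of reads taken by miR-148a-3p and miR-151-3p in A30P. At equal depth both were called higher in 20 of 20 draws with either scaling (mean log2 fold change 6.53 and 6.70 with the deposited scaling). These values argue against the number of reads as the whole cause, but thinning leaves in place anything that went with depth. The relation within groups did not decide it for miR-148a-3p, whose share rose with depth within WT (Pearson r = 0.88, exact permutation p = 0.00585, adjusted over 6 relations 0.0159, Spearman rho = 0.69, p = 0.0694, adjusted 0.139, r = 0.51 without WT 1 and 8, n = 8) but ran the other way within A30P without passing (r = -0.61, p = 0.203, adjusted 0.225, rho = -0.11, p = 0.840, adjusted 0.840, r = -0.13 without A30P 6 and 8, n = 7). For miR-151-3p the share was lower in deeper libraries, as depth or something that went with it would give, past the threshold within A30P (r = -0.97, p = 0.00675, adjusted 0.0159, rho = -0.86, p = 0.0238, adjusted 0.110, r = -0.88 without A30P 6 and 8) and not within WT (r = -0.66, p = 0.223, adjusted 0.225, rho = -0.50, p = 0.216, adjusted 0.324, r = 0.02 without WT 1 and 8), so depth may be part of the cause there. Against RNA from liver, where miR-148a-3p and miR-122-5p are abundant, miR-122-5p, miR-192-5p and miR-194-5p together took at most 0.0301% of the reads of an A30P library. A sequence-dependent difference in library preparation or run may be part of the cause. Across 93 hairpins the log2 fold changes of both arms had no positive relation (Spearman rho -0.18), which met the criterion set before for such a difference. That rho does not mean that most arms moved in opposite directions, since only 13 of the 93 hairpins passed in that way. Missing reads of low arms also weaken the relation. Over the 6 hairpins with reads of both arms in all A30P libraries, a condition added after the result was seen, rho was 0.37. Opposite arms remained at equal depth with the deposited scaling for 1 hairpin, miR-30a, in each of 20 draws, which argues against depth there, whereas depth stays open for the other 12 and scaling for miR-30a, whose 5p arm did not pass in edgeR with TMM scaling at full depth, and preparation, run and genotype cannot be told apart in this design.

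The third pattern was miR-101a-3p, higher in A30P under some settings. Within WT, deeper libraries had higher log2 values (Pearson r = 0.91, exact permutation p = 0.00794, adjusted over the same 6 relations 0.0159, Spearman rho = 0.76, p = 0.0368, adjusted 0.110, r = 0.59 without WT 1 and 8), and within A30P the relation ran the same way without passing (r = 0.48, p = 0.225, adjusted 0.225, rho = 0.36, p = 0.444, adjusted 0.533, r = 0.45 without A30P 6 and 8), which argues against shallow depth as the source of higher A30P values. At equal depth the log2 fold change was 1.07 in the median draw (edgeR adjusted p = 0.138) with the deposited scaling and 2.06 (adjusted p = 0.00288) with TMM scaling. At full depth edgeR with the deposited scaling also gave 1.07 (adjusted p = 0.120). The relation and the difference both rest in part on WT 1 and 8, and whether these libraries differ in biology or in handling was not tested.

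Values far from the rest of their group gave 25 entries over 138 groups tested. Chance would give about 1 in 20 groups only for normally distributed values, which miRNAs listed at 0 in shallow libraries are not. For let-7e-3p, let-7c-1-3p, miR-7a-1-3p and miR-7a-2-3p all A30P libraries but replicate 6 were at 0. Of the 25 entries, 11 were in A30P replicate 6, the deepest A30P library. That library held 3500431 reads (next 441177), 11.6% of reads as miR-148a-3p (next lowest 34.8%), and log2(normalized + 1) values that were low for miR-151-3p (13.73) and miR-1981-5p (11.13) and high for miR-30d-5p (9.92), miR-26a-5p (12.92), miR-410-3p (4.37), let-7e-3p (3.45), let-7c-1-3p (2.51), miR-7a-1-3p and miR-7a-2-3p (3.33 each). A30P replicate 4, the shallowest, was low for miR-101a-3p (8.15) and let-7d-5p (8.82) and at 0 for miR-124-3p and miR-218-5p. A30P replicate 7 was at 0 for miR-434-3p, miR-21a-5p and miR-29a-3p. In WT, replicate 8 had 2.06% of reads as miR-151-3p (next 0.701%) and was low for let-7d-5p (11.99), miR-451a (4.35) and let-7c-1-3p (3.50), replicate 1 was high for miR-125a-5p (15.75), and replicate 3 was high for miR-204-5p (11.71) and miR-183-5p (3.88).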

How the results depend on the processing

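The count tests, TMM and total scaling and the fits without the 4 shallow A30P libraries or without WT libraries 1 and 8 were chosen after seeing the data. The 314 calls stayed within 1.5-fold under the limma settings, with 225 at a mean of at least 10 (296 tested), 276 at adjusted p 0.01, 335 with total scaling, 263 with TMM scaling, 238 without the A30P libraries under 100000 reads, and 299 to 325 (28 to 34 higher, 267 to 293 lower) with each library left out. They moved to 174 by the authors' deposited adjusted p (39 higher, 135 lower), 173 by edgeR with TMM scaling (62 and 111) and 164 by limma-voom with TMM scaling (77 and 87). With the deposited size factors edgeR gave 261 calls (43 higher, 218 lower, 363 tested), so within edgeR TMM scaling, with 313 tested, lowered the count, and DESeq2 gave 238 (47 and 191). For the authors' values and limma-voom the cause was not tested.

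For miR-101a-3p the log2 fold change stayed above 0 under every alternative run. It passed with a pseudocount of 10 (1.56), the replicate block (1.92), the authors' deposited adjusted p (2.96), edgeR (2.58) and limma-voom (2.70) with TMM scaling and limma with TMM scaling (2.72), and ranged from 1.21 to 2.02 with each library left out (adjusted p from 0.0138 to 0.101). Of the lists, 2 passed in camera, 0 with an estimated correlation (2 at unadjusted p under 0.05), 1 with a mean of at least 10, 0 with TMM scaling and 1 without WT libraries 1 and 8. The filter leaves the Hox-linked list with too few members to be tested. Elsewhere the cause was not tested.

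Of the 63 other named miRNAs, 30 kept direction and side of the threshold under all 30 alternatives, among them the first 10 in each direction. Over all alternatives 1732 of 1890 values did so, 52 lost and 52 gained a call, and 54 changed sign, 44 of them without a call on either side. The fit without a filter could change none of these values, since all listed miRNAs had passed the filter. Rescaling by the median ratio moved the median log2 fold change by only 0.01. The fits with a single library left out share most of their libraries with the main fit. Calls were lost in the authors' deposited table by miR-124-5p, miR-129-2-3p, miR-132-3p, miR-145a-5p, miR-146a-5p, miR-204-5p, miR-20a-5p, miR-212-5p, miR-21a-5p, miR-338-3p, miR-34b-3p and miR-7a-1-3p, in edgeR with TMM scaling by miR-124-5p, miR-126a-3p, miR-129-2-3p, miR-145a-5p, miR-204-5p, miR-212-3p, miR-212-5p, miR-23a-3p, miR-486a-3p and miR-7a-1-3p, and in limma-voom by let-7c-1-3p, miR-145a-5p, miR-17-5p, miR-20a-5p, miR-212-5p, miR-34b-3p and miR-7a-2-3p. Without the 4 shallow A30P libraries those of miR-124-5p, miR-126a-3p, miR-145a-5p, miR-206-3p, miR-212-3p and miR-486a-3p were lost, with the deposited size factors in edgeR and DESeq2 those of miR-212-3p and miR-486a-3p (in DESeq2 also miR-7a-1-3p), in limma with TMM scaling those of miR-212-5p and miR-486a-3p, and without WT libraries 1 and 8 that of miR-451a. Calls were gained upward by miR-7a-5p, miR-375-3p and miR-1a-3p with TMM scaling in edgeR and limma-voom and in the authors' deposited table and by miR-7a-5p in limma with TMM scaling. Downward they were gained by miR-132-5p, miR-153-3p, miR-218-5p, miR-219a-2-3p and miR-34c-5p with total scaling, without WT libraries 1 and 8 and without some single libraries, by miR-101b-3p with total scaling, by miR-7b-5p without WT libraries 1 and 8, by miR-486b-5p in the authors' deposited table, with the deposited size factors by miR-132-5p, miR-153-3p and miR-218-5p in edgeR and DESeq2 and by miR-34c-5p in DESeq2, and with pseudocounts of 0.1 and 10 by miR-153-3p and miR-218-5p. By limma-voom with TMM scaling the log2 fold change was 0.81 for miR-101b-3p, 0.32 for miR-153-3p, 0.0861 for miR-7a-1-3p, 0.83 for miR-7b-5p, 0.0394 for miR-124-5p, 0.29 for miR-132-5p, 0.72 for miR-212-3p, 0.51 for miR-219a-2-3p, 0.68 for miR-486a-3p and 0.81 for miR-486b-5p. By edgeR with TMM scaling it was 0.69 for miR-101b-3p, 0.75 for miR-7b-5p, 0.26 for miR-132-5p, 0.46 for miR-219a-2-3p and 0.0351 for miR-486b-5p, and by limma with TMM scaling 0.78 for miR-7b-5p, 0.19 for miR-132-5p, 0.39 for miR-219a-2-3p and 0.73 for miR-486b-5p. In the authors' deposited table it was 0.50 for miR-101b-3p, 1.10 for miR-34c-5p, 1.55 for miR-7b-5p, 0.0966 for miR-132-5p, 0.62 for miR-218-5p, 0.92 for miR-212-3p, 0.0566 for miR-23a-3p, 0.33 for miR-219a-2-3p, -0.41 for miR-451a, 0.0625 for miR-126a-3p and -0.0553 for miR-206-3p. Without the 4 shallow A30P libraries it was 0.18 for miR-7b-5p and -0.0715 for miR-451a, and without WT libraries 1 and 8 it was -0.13 for miR-7a-5p, 0.0802 for miR-486b-5p, -0.33 for miR-375-3p and -0.57 for miR-1a-3p. miR-375-3p was at -0.46 with a pseudocount of 0.1, -0.15 with the replicate block, -0.59 with total scaling and -0.38 to 0.96 with each library left out, and miR-1a-3p at -0.60 with total scaling and -0.29 to 0.54 with each library left out. In limma with TMM or total scaling only the scaling was changed, and elsewhere the cause was not tested.

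No pairing of the samples by replicate number was seen: deviations of same-numbered samples correlated above 0.1 in 2 of 7 pairs, and 1 of 7 A30P samples correlated best with its own number. With 4 A30P libraries under 100000 reads, this check could have missed a pairing. With the replicate block 297 miRNAs passed (28 higher, 269 lower), the call of miR-451a was not made (adjusted p = 0.0545), and the list calls did not change.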

Other observations

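The test reported here was chosen only after the result was seen, as were the miRNAs of the first paragraph. Further miRNAs with reads in all 7 A30P libraries also passed. miR-30c-5p fell from 10079 ± 3948 to 645 ± 775 normalized counts (log2 fold change -4.46, adjusted p = 5.2e-07 by limma), miR-181a-5p from 6686 ± 2125 to 540 ± 625 (-4.11), miR-103-3p from 2843 ± 1284 to 236 ± 289 (-4.11), and miR-99a-5p, transcribed near miR-125b-2, from 35392 ± 7055 to 6870 ± 3832 (-2.52). miR-9-5p, the most abundant of the neuron list in WT, fell from 60492 ± 36673 to 12435 ± 12390, a difference that did not pass in edgeR with TMM scaling (adjusted p = 0.102). Both arms of miR-99b rose with the deposited scaling, the 3p arm from 65.0 ± 22.8 to 290 ± 97.8 and the 5p arm from 7620 ± 4439 to 13123 ± 2052, and the rise of the 5p arm did not pass with scaling to the total of listed reads (adjusted p = 0.610). miR-1298-3p rose from 39.2 to 184 normalized counts (log2 fold change 2.15, adjusted p = 0.0034).

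The log2 fold changes in the authors' deposited table had the same sign as those of limma for 300 of 396 miRNAs and correlated with the log2 ratio of group means at Pearson r = 0.70 across 395 miRNAs, which are not independent replicates. A covariate in the authors' model that follows WT libraries 1 and 8 was tested as a hypothesis, and the test did not decide it. The difference between the deposited value and the log2 ratio of means correlated with the contrast of WT 1 and 8 against the other 6 WT libraries at r = -0.73 across miRNAs, but both measures hold the same WT values, and the other pairs of WT libraries gave r from -0.71 to 0.73, with 2 of 28 pairs at least as large in size. Whether a covariate was used is not given in the sources used here. miR-101a-3p, with its lowest WT values in those 2 libraries, is among the miRNAs whose deposited log2 fold change (2.96) exceeded the log2 ratio of means (1.06).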
